A study of Homo sapiens with 6 samples.

How the data were processed

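RNA was measured in AGS cells, a line derived from a human gastric adenocarcinoma, on Affymetrix whole-transcript gene arrays. Per the labels, 3 cultures received 5 µM PD98059 and 3 received the solvent DMSO, total RNA was taken after 48 h, and 500 ng of it was turned into biotin-labelled sense cDNA for each array. The labels call the 3 arrays of each group biological replicates. Each array is 1 sample, and no column of values was left without a sample.

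The deposited table holds 1 log2 value per probe set and array, made with RMA in Affymetrix Expression Console 1.4.1.46, per the submitters' processing notes. RMA corrects the background, normalizes the probes by quantiles and summarises them by median polish, and the notes give no option or probe annotation. The log2 scale was read from the deposited values themselves, which run from 0.12 to 13.63 and are written with 2 decimals. No genome build is given in the sources used here, so no coordinates are printed. The deposited values were used without a further transformation, although the arrays still differed in their spread. Scanner files and detection calls were not used here, so a dim probe set could not be compared with its background, and the number of arrays limits the precision.

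The table has 33297 probe sets. Of these, 21214 are in the platform table used to name them, and 12083 are not and are unnamed here. A further 1754 carry several gene symbols and were left out of the tests. The other 19460 carry 1 symbol, and 19429 of these matched the RefSeq table of assembly GRCh38.p14 by Entrez identifier, with 0 symbols changed. The probe set with the highest mean over the 6 arrays stood for each of the 769 genes with more than 1, which gave 18417 tested genes.

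Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no covariate), and p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. All tests were two-sided. Gene lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 38 lists. An adjusted p "with an estimated correlation" comes from camera with the correlation between the members of a list estimated from the arrays. The degrees of freedom then come from the arrays, whereas with the preset correlation they come from the number of genes. A lost call can therefore reflect the few arrays as well as members that move together. For small nucleolar RNAs the estimated correlation was below 0.01, yet the unadjusted camera p went from 6.40e-06 to 0.00155. The limma function fry tests whether the members move one way on balance, or in its mixed form either way, without comparing them with other genes. Single values per array, such as the median of a list, were compared by an exact permutation test, whose smallest possible p with 3 arrays against 3 is 0.1. The median of a list was also placed among 10000 random lists of the same size, drawn from 50 bins of mean level so that the random genes were as bright. Figures were drawn with matplotlib 3.10.9.

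The 38 lists, the tests and the alternatives were fixed before the data were examined. The lists cover ERK output, immediate early genes, components of the MAPK pathway, receptor tyrosine kinases with their ligands and adaptors, the cell cycle (G1/S and DNA replication, mitosis, histones), p53 targets, apoptosis, DNA repair, stress responses (NRF2, unfolded protein, heat shock), aryl hydrocarbon receptor targets, lipid and sugar metabolism, ribosome biogenesis, ribosomal proteins, small nucleolar RNAs, respiration, lysosomes, interferon, NF-kB, MHC, invasion, epithelial and mesenchymal genes, gastric and intestinal lineage, WNT, Hippo and FOXO targets, and markers of fibroblasts, leukocytes, endothelium and erythroid cells. Members without a tested probe set were not analysed here. The list meant for mitochondrially encoded genes is void: its name pattern took 2 other sequences.

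The rule for named genes was also fixed before the data were examined. In each direction it took the 12 genes of largest change among those past the adjusted threshold with non-overlapping groups, filled up with the genes of smallest unadjusted p where fewer passed, and skipped unnamed loci, small RNAs and Y-linked genes. It added up to 4 members of each described list, those of smallest unadjusted p, and 18 genes fixed by name around MEK and ERK signalling, the aryl hydrocarbon receptor and the cell cycle. Because 0 genes passed, the 12 genes in each direction are those of smallest unadjusted p.

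The alternatives fixed beforehand were the replicate number as a block, centring each array again, quantile normalization of the tested genes, 2 filters on dim genes (below the 30th percentile and below the median level), all probe sets, the mean of a gene's probe sets, an intensity trend or a robust prior in eBayes, array weights, leaving out each array in turn, a 1.5-fold minimum with the unadjusted threshold, and for the lists an estimated correlation, fry and camera on ranks. Quantile normalization for the lists, the same with an estimated correlation or with fry, leaving out the PD98059 arrays 2 and 3 together, and quantile normalization without the PD98059 array 1 or with array weights were chosen after seeing the data. For each count the 10 ways to split the 6 arrays into groups of 3 were run as well.

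The gene and list tests were checked on simulated arrays with the real genes' levels. The spread of each gene was drawn from the distribution that limma fitted to the real genes, and the genes varied independently. Of 18417 simulated genes, 200 were changed, 50 at each size, and the genes of the ERK output list were lowered by a further 0.5 on the log2 scale, which camera called with 0 other lists. At an adjusted p under 0.05, limma recovered 2% of those changed by 0.5 on the log2 scale, 28% of those changed by 1, 98% of those changed by 2 and 100% of those changed by 3, and it called 7 unchanged genes. Among the unchanged genes, 4.94% had an unadjusted p under 0.05. When some simulated arrays were given a narrower spread and no gene was changed, camera called 11 lists, and 0 after quantile normalization. Because the simulated genes were independent, neither check shows how camera at 0.01 behaves where the members of a list move together. In the real arrays the estimated correlation was 0.110 for ERK output, 0.533 for ribosome biogenesis and -0.0028 for small nucleolar RNAs.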

Results

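The 6 arrays measured the transcripts of AGS gastric cancer cells after 48 h with 5 µM PD98059 (3 arrays) or with its solvent DMSO (3 arrays). PD98059 blocks the activation of MEK, the kinase that phosphorylates ERK, and the comparison asks which transcripts differ between the drug and its solvent. The arrays do not measure ERK phosphorylation, so how far the pathway was inhibited at 48 h is not known here. Over the 18417 tested genes the arrays had medians between 2.67 and 2.71 on the log2 scale and correlated with each other between 0.953 and 0.988. The PD98059 array 1 correlated with the DMSO arrays 1, 2 and 3 at 0.988, 0.981 and 0.980. With the PD98059 arrays 2 and 3 it correlated less, at 0.974 and 0.961. The spread over genes (SD) was 1.89, 1.74 and 1.80 in the DMSO arrays and 1.84, 1.65 and 1.58 in the PD98059 arrays. The mean spread was 1.81 ± 0.07 with DMSO and 1.69 ± 0.13 with PD98059 (SD, n = 3 each, exact permutation p = 0.3, where 0.1 is the smallest possible). In the PD98059 arrays 2 and 3, bright genes read lower as a class: the brightest of 10 classes of genes by level had a median difference from the DMSO mean of -0.35 and -0.51 there, against -0.02 in the PD98059 array 1. For this reason the values of many lists and of some genes after a further quantile normalization are set beside those as deposited. The other differences of single genes are given as deposited only.

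**Figure D1:**
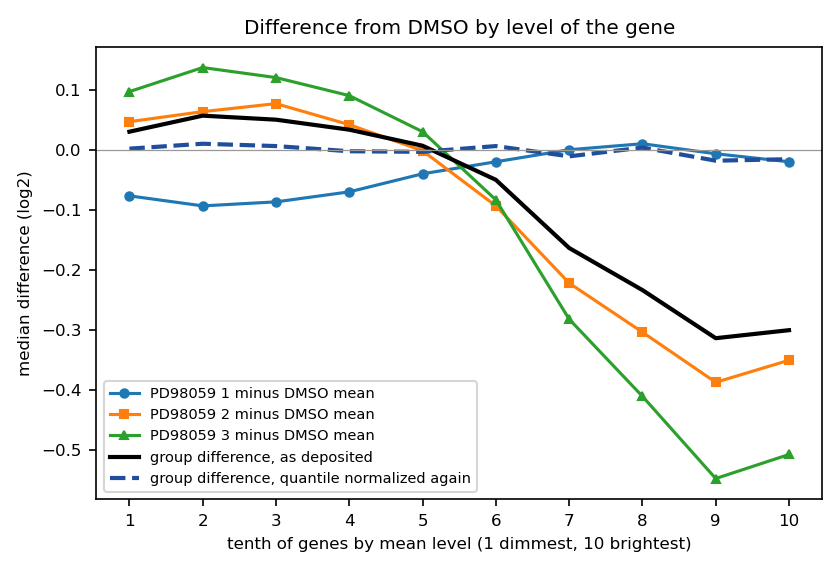
Median difference from the DMSO mean (log2, vertical axis) for genes in 10 classes of mean level (horizontal axis, dimmest to brightest), for each PD98059 array as deposited and for the group difference before and after quantile normalization. In the brightest class the group difference is -0.30 as deposited and -0.016 after quantile normalization.

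CYP1A1, the cytochrome that oxidises aromatic hydrocarbons, had the smallest unadjusted p of all tested genes. Its level (probe set 7990391) was 2.72 ± 0.30 with DMSO and 4.32 ± 0.13 with PD98059 (log2, mean ± SD, n = 3 each), a 3.04-fold difference of 1.60 (SE 0.20). REG1A, a secreted lectin-like protein of the digestive tract (probe set 8042986), was at 6.69 ± 0.49 and 8.32 ± 0.22, a difference of 1.63 (SE 0.25). The difference was 1.01 (SE 0.18) for the secreted phospholipase PLA2G2A, 0.97 (SE 0.16) for the sodium pump subunit ATP1B1, 0.95 (SE 0.20) for GATM, which makes the precursor of creatine, and 0.92 (SE 0.18) for the ornithine aminotransferase OAT. The apolipoprotein APOA2 differed by 1.21, the transcription factor IRF8 by 1.09, the dynein light chain DYNLL1 by 0.88 and the zinc finger gene ZNF821 by 0.73. For DYNLL1 this is the brighter of its 2 probe sets. PSG11 (1.39) belongs to a family of closely similar genes and RPS6P6 (0.92) is a pseudogene, so the source of their signal is uncertain. In each of these 12 genes all 3 PD98059 arrays lay above all 3 DMSO arrays.

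DUSP6, a phosphatase that acts on ERK, had the largest difference among the 12 genes of smallest unadjusted p with a lower level. It (probe set 7965335) was at 4.59 ± 0.19 with DMSO and 3.07 ± 0.54 with PD98059 (n = 3 each), a 2.87-fold difference of -1.52 (SE 0.26). ANKRD1, a target of the Hippo effector YAP (probe set 7934979), IER3, an immediate early gene, and HOXB9, a homeobox gene, differed by -1.45 (SE 0.19), -1.45 (SE 0.22) and -1.44 (SE 0.27). For IER3 this is the brightest of its 3 probe sets. The difference was -1.18 (SE 0.18) for the perforin gene PRF1, -1.10 (SE 0.20) for the membrane protein TM4SF1, -1.10 (SE 0.21) for the adhesion molecule L1CAM and -1.05 (SE 0.19) for the LIM protein CSRP2. PPL, the plakin periplakin, differed by -0.97, MYEOV by -0.93, the protocadherin PCDHGB4 by -0.92 and the homeobox gene MEIS3 by -0.88. All 3 PD98059 arrays lay below all 3 DMSO arrays in each of these 12 genes, as the plot of single arrays shows.

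**Figure D2:**
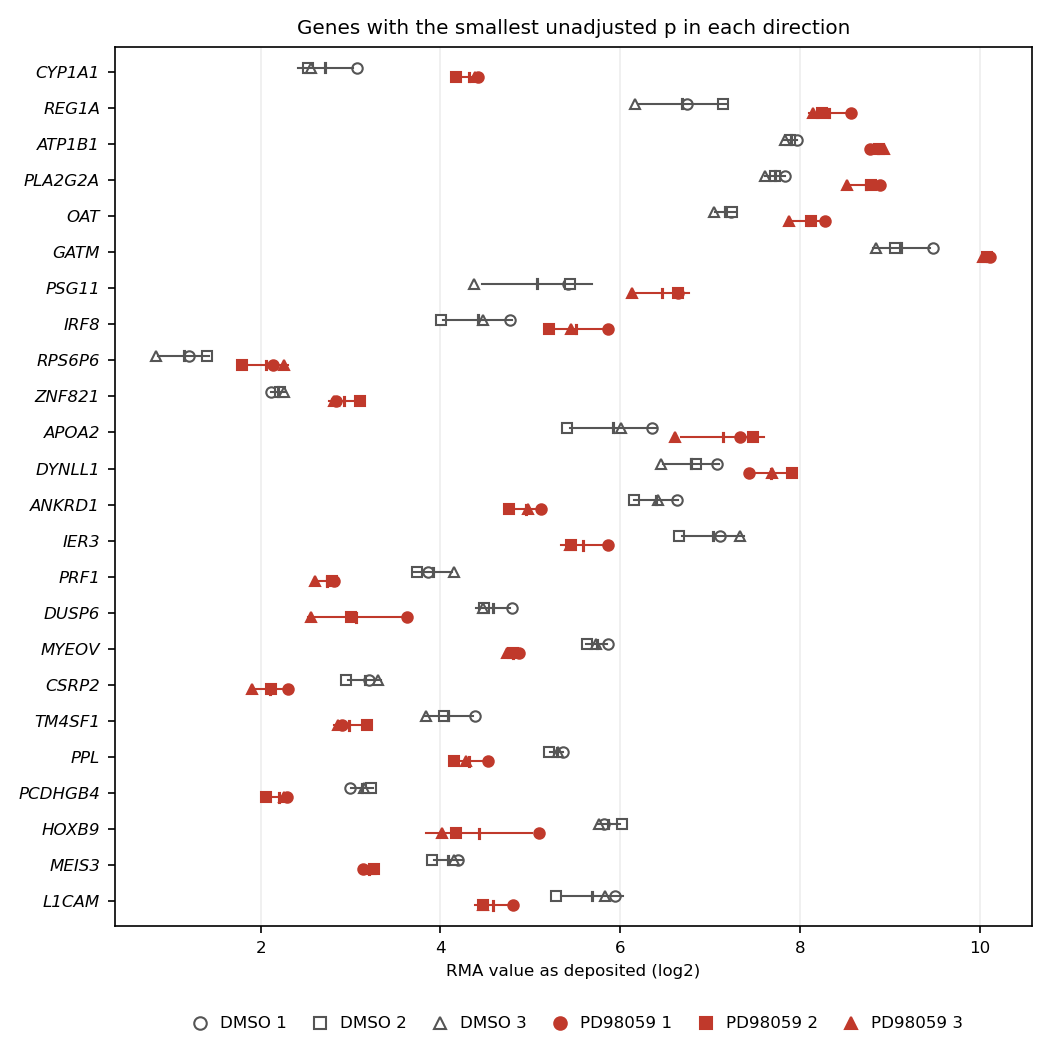
RMA values as deposited (log2, horizontal axis) of the 12 genes of smallest unadjusted p in each direction (vertical axis), 1 open symbol per DMSO array and 1 filled symbol per PD98059 array, with a tick at each group mean and a line of 1 SD to each side. The 2 groups do not overlap in any of the 24 genes, which were picked for small p-values; CYP1A1 lies at 2.72 on average with DMSO and 4.32 with PD98059.

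None of these differences passed the adjusted threshold over all genes. With limma and Benjamini-Hochberg, 0 of the 18417 genes had an adjusted p under 0.05, the smallest being 0.188 for CYP1A1 and ANKRD1, while 1836 genes (9.97%) had an unadjusted p under 0.05 where chance gives 921. Of these, 297 were higher and 1539 lower (83.8% lower), and after quantile normalization 733 were higher and 911 lower (55.4% lower), again with 0 past the adjusted threshold and a smallest adjusted p of 0.0827. CYP1A1 then differed by 1.77, REG1A by 1.87, DUSP6 by -1.41, ANKRD1 by -1.13 and IER3 by -1.14. The 2 groups did not overlap in 2155 genes (11.7%), where chance gives 10%. Without the PD98059 array 1, limma called 572 genes (68 higher, 504 lower), among them 6 of the 12 named higher and 12 of the 12 named lower genes, and leaving out any other array gave 0. After quantile normalization the same setting called 1 gene, PSPH (-2.16, named after its values were seen), and 0 of the named genes. With array weights, which gave that array a weight of 0.39 and the PD98059 array 2 one of 3.17, limma called 2086 genes (347 higher, 1739 lower), and after quantile normalization with array weights it called 6: CYP1A1, REG1A, PLA2G2A, ATP1B1 and OAT higher and ANKRD1 lower.

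The ERK output list, 29 measured genes whose transcription follows ERK activity, fell with PD98059. Its median difference was -0.48 (camera in limma, adjusted p = 3.54e-07 over 38 lists). The call was lost with an estimated correlation (adjusted p = 0.408 with an estimated correlation). Of the 29 genes, 15 were lower at an unadjusted p under 0.05, 0 were higher and 14 did not pass, and 25 of the 29 differences were negative. There were 11 genes that fell when adjusted over the list alone (CCND1, DUSP4, DUSP6, EGR1, EPHA2, EPHA4, ETV4, ETV5, IER3, PHLDA1 and TNFRSF12A), against 0 over all genes tested. The phosphatase DUSP4 and the ETS factor ETV4 both differed by -1.04 (SE 0.23 and 0.26), ETV5 by -0.76 (SE 0.27), PHLDA1 by -0.75 (SE 0.19), the cyclin D1 gene CCND1 by -0.75 (SE 0.21) and EGR1 by -0.67 (SE 0.20). Members that did not pass even within the list included the feedback inhibitors SPRY4 (-0.64, SE 0.24) and SPRY2 (-0.27, SE 0.25), MYC (-0.48, SE 0.25) and FOSL1 (-0.11, SE 0.17), which turned to 0.21 after quantile normalization. The genes of the drug's target kinases, MAP2K1 and MAP2K2, differed by -0.72 (SE 0.36) and -0.42 (SE 0.18) as deposited. After quantile normalization MAP2K2 turned to 0.017 without the PD98059 array 1 and to 0.016 with array weights.

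**Figure D3:**
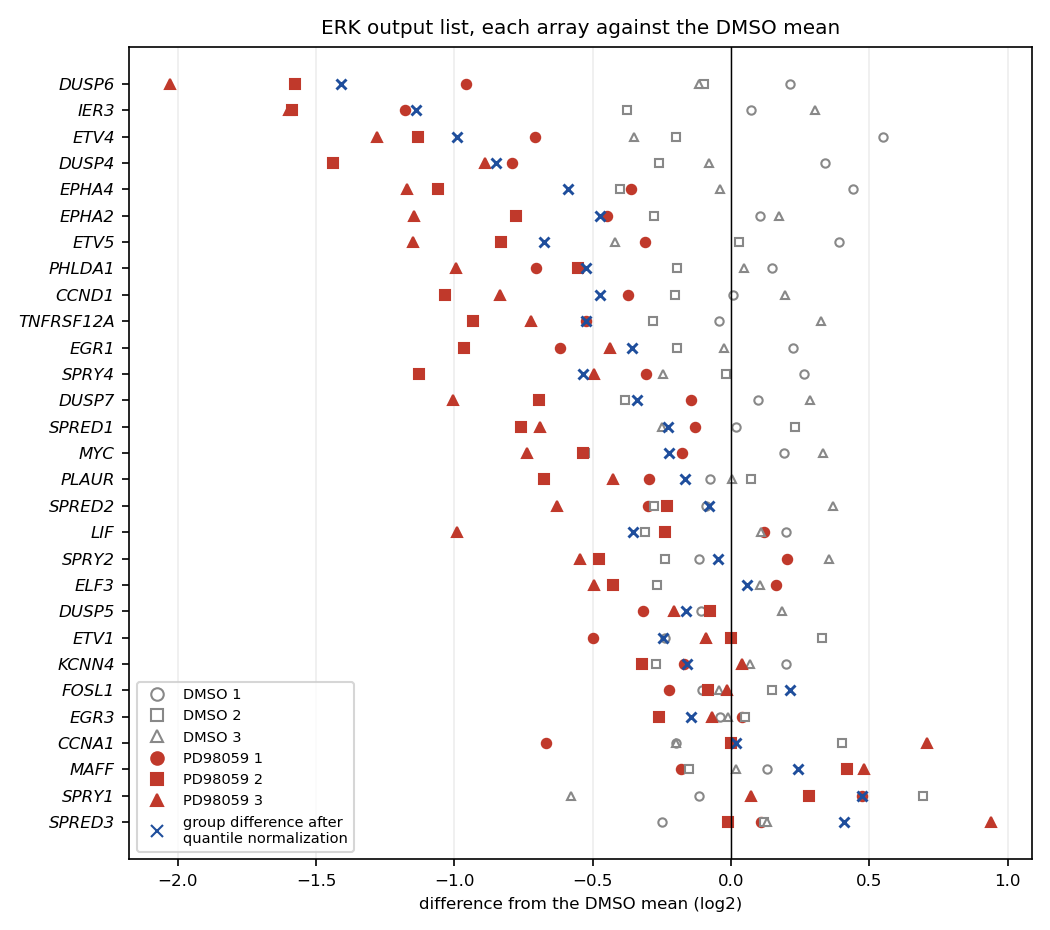
Difference of each array from the DMSO mean (log2, horizontal axis) for the 29 genes of the ERK output list (vertical axis), with open symbols for DMSO arrays, filled symbols for PD98059 arrays and crosses for the group difference after quantile normalization. The median of the list is -0.48 as deposited and -0.25 after quantile normalization, and the lowest differences are those of DUSP6.

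After quantile normalization the ERK output list still fell, with a median of -0.25 (adjusted p = 6.96e-06, and adjusted p = 0.103 with an estimated correlation). At that point 7 genes fell when adjusted over the list alone: DUSP4, DUSP6, EPHA2, EPHA4, ETV4, IER3 and PHLDA1. The median of the list's differences was -0.31, -0.55 and -0.63 in the PD98059 arrays 1, 2 and 3 as deposited and -0.30, -0.34 and -0.21 after quantile normalization. Per array, the median level of the list was 4.60 ± 0.13 with DMSO and 4.04 ± 0.33 with PD98059 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Over all 38 lists, camera called 18 as deposited (14 lower, 4 higher) and 6 of these 18 after quantile normalization (5 lower, 1 higher). With an estimated correlation it called 0 in either scaling (smallest adjusted p = 0.0589 as deposited), and fry called 0 as deposited (smallest adjusted p = 0.186). After quantile normalization fry called 4: ERK output and cholesterol synthesis lower (adjusted p = 0.0265 for both), Hippo YAP targets lower and the interferon response higher (adjusted p = 0.04997 for both).

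Camera called 3 lists of lipid and sugar metabolism lower in both scalings, with the preset correlation only. Cholesterol synthesis (20 genes) had a median of -0.43 (adjusted p = 1.85e-05 by camera, adjusted p = 0.532 with an estimated correlation) and -0.16 after quantile normalization (adjusted p = 0.0149, adjusted p = 0.337 with an estimated correlation). In it 8 genes were lower at an unadjusted p under 0.05, and adjusted over the list alone 4 fell against 0 over all genes: DHCR7 (-0.95, SE 0.22), the mevalonate kinase MVK (-0.92, SE 0.21), INSIG1 (-0.87, SE 0.23), which holds back the activation of sterol-sensing transcription factors, and NSDHL (-0.61, SE 0.18). After quantile normalization 2 of these, DHCR7 and MVK, still passed. Glycolysis and hypoxia (29 genes) had a median of -0.33 (adjusted p = 2.39e-05, adjusted p = 0.532 with an estimated correlation) and -0.19 after quantile normalization (adjusted p = 0.000464, adjusted p = 0.337 with an estimated correlation). Here 11 genes were lower at an unadjusted p under 0.05 and adjusted over the list alone 4 fell, again with 0 over all genes: the glucose transporter SLC2A1 (-1.05, SE 0.21), PFKP (-0.74, SE 0.19), ENO1 (-0.70, SE 0.19) and the pyruvate kinase PKM (-0.69, SE 0.19). After quantile normalization 1 of these, SLC2A1, still passed. Fatty acid synthesis and lipid storage (23 genes) had a median of -0.27 (adjusted p = 0.0113, adjusted p = 0.532 with an estimated correlation) and -0.24 after quantile normalization (adjusted p = 0.0499, adjusted p = 0.337 with an estimated correlation). None of its genes passed when adjusted over the list alone (0 of 23), and the synthesis enzymes ACLY and FASN differed by -0.80 (SE 0.25) and -0.70 (SE 0.27). Without the DMSO array 1 this list lost its call (adjusted p = 0.0501). After quantile normalization the median of cholesterol synthesis lay at percentile 2.79 of 10000 lists of equally bright genes, that of glycolysis at 0.1 and that of fatty acid synthesis at 0.02. The median level of cholesterol synthesis per array was then 5.26 ± 0.06 with DMSO and 5.21 ± 0.06 with PD98059 (SD, n = 3 each, exact permutation p = 0.4). For fatty acid synthesis it was 3.35 ± 0.09 and 3.23 ± 0.17 (exact permutation p = 0.3), and for glycolysis the exact permutation p was 0.1.

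A mixed list of receptor tyrosine kinases, ligands and adaptors (24 genes) was also called lower. It holds the EGFR family with its ligands and the inhibitor ERRFI1, and beside them AXL, MET, HGF, PDGFRB, FGFR1 to FGFR4, IGF1R, INSR, IRS1 and IRS2. Its median was -0.26 (camera in limma, adjusted p = 0.0154, adjusted p = 0.532 with an estimated correlation) and -0.16 after quantile normalization (adjusted p = 0.0149, adjusted p = 0.357 with an estimated correlation). In the list 5 genes were lower at an unadjusted p under 0.05, and adjusted over the list alone 1 fell against 0 over all genes: IRS1 (-1.13, SE 0.26), an adaptor of the insulin and IGF1 receptors. EGFR itself differed by -0.84 (SE 0.27), its ligand HBEGF by -0.62 (SE 0.24) and the EGFR inhibitor ERRFI1 by -0.49 (SE 0.19).

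A further 9 lists were called lower by camera as deposited and lost that call after quantile normalization. The immediate early genes (26) had a median of -0.27 (camera in limma, adjusted p = 0.00147, adjusted p = 0.532 with an estimated correlation) and of -0.090 after quantile normalization (adjusted p = 0.0845). Hippo YAP targets (25) had -0.18 (adjusted p = 0.0102, adjusted p = 0.532 with an estimated correlation) and -0.11 (adjusted p = 0.0845). Of the immediate early genes 5 fell when adjusted over the list alone (CCN1, CCN2, EGR1, IER3 and ZFP36), and of the Hippo targets 3 (ANKRD1, CCN1 and CCN2), each against 0 over all genes. After quantile normalization 1 gene of each list still passed, IER3 and ANKRD1. The matricellular genes CCN2 and CCN1, members of both lists, differed by -0.83 (SE 0.19) and -0.62 (SE 0.17), and ZFP36, which destabilises mRNA, by -1.39 (SE 0.40). Components of the MAPK pathway (26) had a median of -0.31 (adjusted p = 0.00153, adjusted p = 0.642 with an estimated correlation) and -0.076 after quantile normalization (adjusted p = 0.0845), with SHC1 at -1.05 (SE 0.32). The p53 targets and CDK inhibitors (28) had -0.26 (adjusted p = 0.00252, adjusted p = 0.532 with an estimated correlation) and -0.11 (adjusted p = 0.0988). Their median level per array after quantile normalization went the other way, 4.42 ± 0.07 with DMSO and 4.53 ± 0.02 with PD98059 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). GDF15 (-0.82, SE 0.19) was the 1 gene that fell when adjusted over the list alone, and CDKN1A differed by -0.68 (SE 0.24).

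The other 5 of those 9 lists cover growth, division, respiration and protein folding. G1/S and DNA replication (39 genes) had a median of -0.30 as deposited (camera in limma, adjusted p = 0.00401, adjusted p = 0.646 with an estimated correlation) and -0.089 after quantile normalization (adjusted p = 0.537). The thymidine kinase TK1 was at -0.59 (SE 0.21) and the replication clamp PCNA at -0.55 (SE 0.21). Mitosis (40) had -0.22 (adjusted p = 0.00748, adjusted p = 0.646 with an estimated correlation) and 0.065 (adjusted p = 0.913), where the mean (-0.012) had the other sign, with the kinase PLK1 at -0.96 (SE 0.26) and the proliferation marker MKI67 at -0.44 (SE 0.25). Ribosome biogenesis and MYC targets (27) had -0.29 (adjusted p = 0.00166, adjusted p = 0.646 with an estimated correlation) and -0.047 (adjusted p = 0.421). Oxidative phosphorylation (28) had -0.24 (adjusted p = 0.00674, adjusted p = 0.646 with an estimated correlation) and 0.014 (adjusted p = 0.710; mean -0.016). The unfolded protein response and ATF4 targets (31) had -0.27 (adjusted p = 0.0428, adjusted p = 0.646 with an estimated correlation) and -0.13 (adjusted p = 0.315), with the serine pathway enzyme SHMT2 at -0.76 (SE 0.26). In each of these 5 lists 0 genes passed when adjusted over the list alone. Without the DMSO array 1 the adjusted p was 0.106 for G1/S, 0.379 for mitosis, 0.0595 for oxidative phosphorylation and 0.187 for the unfolded protein response. Without the PD98059 array 3 it was 0.0635, 0.134, 0.144 and 0.144, with 0.112 for ribosome biogenesis. The unfolded protein response list also lost its call without the DMSO array 2 (adjusted p = 0.0512) or the PD98059 array 2 (adjusted p = 0.105). Leaving out dim genes below the 30th percentile also ended the calls of G1/S (adjusted p = 0.0598), mitosis (adjusted p = 0.106), oxidative phosphorylation (adjusted p = 0.0598) and the unfolded protein response (adjusted p = 0.324).

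**Figure D4:**
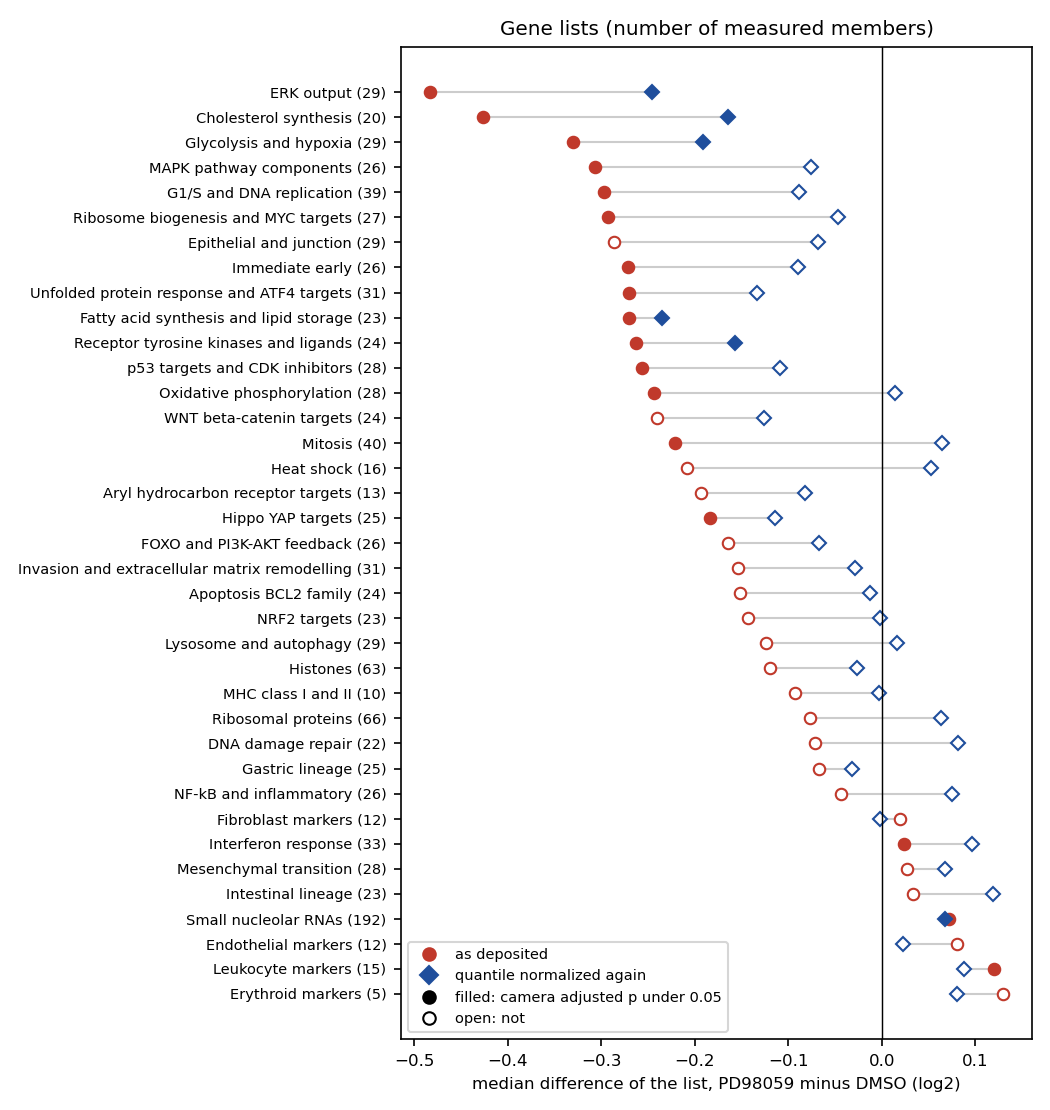
Median difference between PD98059 and DMSO (log2, horizontal axis) for the gene lists other than the void one (vertical axis, with the number of measured genes), with circles as deposited and diamonds after quantile normalization, filled where the camera adjusted p is under 0.05. The ERK output list has the lowest median as deposited (-0.48).

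Small nucleolar RNAs rose as a group by a small amount. The 192 measured RNAs had a median difference of 0.072 (camera in limma, adjusted p = 6.08e-05, adjusted p = 0.0589 with an estimated correlation) and 0.067 after quantile normalization (adjusted p = 0.0147, adjusted p = 0.103 with an estimated correlation). At an unadjusted p under 0.05, 15 were higher and 2 lower, and adjusted over the list alone 0 passed. Many of the 192 are numbered copies of SNORD115 or SNORD116, and camera counted each copy as a separate gene. They are dim on this array: the median level per array was 1.82 ± 0.05 with DMSO and 1.95 ± 0.05 with PD98059 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible), and after quantile normalization 1.84 ± 0.09 and 1.92 ± 0.14 (exact permutation p = 0.5).

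The interferon response list (33 genes) rose as deposited against the other genes, with a median of 0.023 (camera in limma, adjusted p = 0.0115, adjusted p = 0.408 with an estimated correlation) and 0.097 after quantile normalization (adjusted p = 0.0696). Its members went both ways: BST2 differed by 0.66 (SE 0.18) and the immunoproteasome subunit PSMB8 by 0.48 (SE 0.17), and USP18 by -0.65 (SE 0.19) and IRF7 by -0.62 (SE 0.22). Adjusted over the list alone 0 passed. The call was lost without the PD98059 array 1 (adjusted p = 0.0530) and when dim genes below the 30th percentile were left out (adjusted p = 0.0598). Leukocyte markers (15 genes) rose by a median of 0.12 (adjusted p = 0.0277, adjusted p = 0.532 with an estimated correlation), which was 0.088 after quantile normalization (adjusted p = 0.237), at a median level of 2.02 ± 0.17 with DMSO and 2.16 ± 0.25 with PD98059 (SD). Its median difference was -0.03, 0.12 and 0.20 in the PD98059 arrays 1, 2 and 3, positive in the same arrays 2 and 3 that had the narrower spread. Adjusted over the list alone 0 of them passed, and CSF1R, the 1 marker with an unadjusted p under 0.05, differed by 0.47 (SE 0.20). The call was lost without the DMSO array 1 (adjusted p = 0.156) or the PD98059 array 3 (adjusted p = 0.146). The list named for mitochondrially encoded genes was also called (median 0.41, adjusted p = 0.0438, adjusted p = 0.532 with an estimated correlation), but its 2 members are the nuclear gene MND1 and the pseudogene MTND2P28, so it says nothing of mitochondrial transcripts.

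Targets of the aryl hydrocarbon receptor, the regulator of CYP1A1, did not move as a list. The 13 genes had a median of -0.19 (camera in limma, adjusted p = 0.977), and after quantile normalization the median was -0.082 and the mean 0.085 (adjusted p = 0.721). Adjusted over the list alone CYP1A1 rose and ALDH3A1 (-0.75, SE 0.21) and CYP2S1 (-0.74, SE 0.23) fell, of which CYP1A1 alone still passed after quantile normalization. As deposited, fry called the list in its mixed form (adjusted p = 0.00237), the 1 list of 38 called by fry in that form, with 0 called for a balance in one direction. CYP1B1 differed by 0.21 (SE 0.17) and TIPARP by -0.34 (SE 0.24).

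The other 19 lists did not pass. Epithelial and junction genes (29) had a median of -0.29 (camera in limma, adjusted p = 0.132) with KRT19 at -1.15 (SE 0.32) and MUC1 at -0.97 (SE 0.29), and WNT beta-catenin targets (24) had -0.24 (adjusted p = 0.0633) with DKK1 at 0.51 (SE 0.18). Heat shock genes (16) had -0.21 (adjusted p = 0.174) and apoptosis genes of the BCL2 family (24) -0.15 (adjusted p = 0.174). The list of invasion and extracellular matrix remodelling (31) had -0.15 (adjusted p = 0.277), and adjusted over the list alone the integrin genes ITGA3 (-1.16, SE 0.28) and ITGA2 (-0.91, SE 0.20) fell, the only such genes in these 19 lists as deposited, and after quantile normalization neither passed. FOXO and PI3K-AKT feedback (26; -0.17, adjusted p = 0.191), NRF2 targets (23; -0.14, adjusted p = 0.908), lysosome and autophagy (29; -0.12, adjusted p = 0.291), histones (63 with linker histones, an antisense RNA and pseudogenes; -0.12, adjusted p = 0.671) and ribosomal proteins (66; -0.077, adjusted p = 0.610) did not pass either. Gastric lineage (25) had -0.067 (adjusted p = 0.985) and intestinal lineage (23) 0.033 (adjusted p = 0.360), and mesenchymal transition (28) had 0.027 (adjusted p = 0.417). NF-kB and inflammatory genes (26) had -0.043 (adjusted p = 0.671) with ICAM1 at -1.43 (SE 0.40), DNA damage repair (22) -0.072 (adjusted p = 0.693) and MHC class I and II (10) -0.093 (adjusted p = 0.734). Endothelial markers (12) had 0.080 (adjusted p = 0.174), fibroblast markers (12) 0.020 (adjusted p = 0.169) and erythroid markers (5) 0.13 (adjusted p = 0.232).

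For the intestinal and mesenchymal lists the mean was negative (-0.015 and -0.030) where the median and the test pointed up, and for NF-kB, DNA damage repair and MHC genes the test pointed up with a negative median, since camera compares a list with other genes, whose median was -0.057. After quantile normalization, adjusted over the list alone, DKK1 and LGR5 of the WNT list, CDH17 of the intestinal list, B2M of the MHC list and HMOX1 of the NRF2 list rose, each against 0 over all genes. Single arrays decided some of these calls: limma's camera called epithelial genes without the DMSO array 2 (adjusted p = 0.0267), heat shock genes without the DMSO array 3 (adjusted p = 0.0191) or the PD98059 array 1 (adjusted p = 0.0437), WNT targets without the PD98059 array 1 (adjusted p = 0.0437) or 2 (adjusted p = 0.0499), and lysosome genes lower and fibroblast markers higher without the PD98059 array 1 (adjusted p = 0.0326 for both). With all 6 arrays, camera on ranks also called the WNT targets lower (adjusted p = 0.0451).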

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

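The settings with quantile normalization of the lists, with quantile normalization and the PD98059 array 1 left out or array weights, and with the PD98059 arrays 2 and 3 left out were tests chosen after seeing the data; the others were planned, and the cause of a change was not tested unless given. With the replicate block (limma) the genes at an unadjusted p under 0.05 became 539 higher and 2377 lower, and no list call changed. Again 0 genes passed the adjusted threshold, with a smallest adjusted p of 0.0788. Whether the numbers pair the arrays stays open. The deviations of same-numbered arrays correlated at 0.50, 0.17 and 0.054. The PD98059 arrays 1 and 2 correlated best with the DMSO array of their own number, and the PD98059 array 3 with the DMSO array 2 (0.31). Quantile normalization gave 733 higher and 911 lower, and all probe sets 982 higher. Filters on dim genes test fewer genes and left 177 higher above the 30th percentile and 98 above the median level. Array weights gave 1494 higher and 3947 lower, with 347 and 1739 past the adjusted threshold; after quantile normalization they gave 1209 higher, with 5 higher and 1 lower past it. Quantile normalization without the PD98059 array 1 gave 1498 higher, and 1 gene lower past it, the phosphatase gene PSPH (-2.16, named after its values were seen). Leaving out 1 array in turn gave 160 to 956 higher and 643 to 3281 lower, and past the adjusted threshold 0 to 68 higher and 0 to 504 lower, the highest of each without the PD98059 array 1. Without the PD98059 arrays 2 and 3, 200 were lower. At least 1.5-fold with an unadjusted p under 0.05 were 139 higher and 966 lower. For the lists, 14 were called lower and 4 higher as deposited; an estimated correlation and fry left 0 lower and 0 higher each, quantile normalization 5 lower and 1 higher, quantile normalization with an estimated correlation 0 and 0 and with fry 3 and 1, leaving out 1 array 9 to 17 lower and 2 to 4 higher, and leaving out the PD98059 arrays 2 and 3 1 lower and 1 higher. The ERK output list (adjusted p = 3.54e-07) had an adjusted p of 0.408 with an estimated correlation, 0.186 by fry, 0.0265 by fry after quantile normalization and 0.103 with quantile normalization and an estimated correlation, and 3.00e-08 to 7.83e-05 with 1 array left out. Of 3277 results for the 175 named genes under the alternatives, 3260 kept their direction. Those that turned were FOSL1 after quantile normalization (0.21; 0.43 without the PD98059 array 1, 0.31 with array weights), MAP2K2 (0.017 without that array, 0.016 with weights) and NFKB2 (0.034 without that array), and, with the PD98059 arrays 2 and 3 left out, SPRY2 (0.20), TIPARP (0.16), BAK1 (0.050), TAP1 (0.010), TAP2 (0.12), PARP1 (0.020), HLA-DPB1 (-0.043), POSTN (-0.090), COL1A2 (-0.16), CD3D (-0.020) and HBD (-0.010). In that last setting the lists G1/S (adjusted p = 0.592), mitosis (0.944), ribosome biogenesis (0.592) and oxidative phosphorylation (0.592) also turned, uncalled. Of 607 list results under the alternatives, 478 stayed on their side of the threshold, 117 called lists were no longer called and 8 uncalled lists were called. Without a measure of background, dim genes such as the small nucleolar RNAs cannot be placed above it.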

Other observations

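The tests of the collagen genes, of the lists that lost their call, and of the range and the paralog for CYP1A1 were chosen only after the result was seen. The tests of the range and of a single array for the ERK output list use quantile-normalized list values. That normalization of the lists was chosen after seeing the data.

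Among 235 families of at least 10 genes that share a name stem, the collagen genes (44) were the only family called by camera in both scalings, and the only one called higher in either. Their median difference was 0.17 (camera in limma, adjusted p = 0.00070) and 0.20 after quantile normalization (adjusted p = 0.00735). The call was lost with an estimated correlation (unadjusted camera p = 0.30 and 0.31). Of the 44 differences 35 were positive, with 0 at an unadjusted p under 0.05. The median was -0.10, 0.27 and 0.27 in the PD98059 arrays 1, 2 and 3, so it was positive in the same arrays that had the narrower spread. Their median level was at percentile 46.5 of all genes. Among 10000 lists of equally bright genes their median difference lay at percentile 100 in both scalings. The family was picked from the 235 by its calls in these same values, so this percentile does not decide whether the narrower spread was the cause. Among the 12083 unnamed probe sets, 1084 had an unadjusted p under 0.05 where chance gives 604, 698 higher and 386 lower, and 0 passed the adjusted threshold.

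The ERK output list was lower with PD98059, an inhibitor of ERK's activator, in the values of each of the 3 treated arrays. The narrower spread of the PD98059 arrays 2 and 3 is argued against as the whole cause: after quantile normalization the list's median lay at percentile 0.02 of 10000 lists of equally bright genes. A single array is argued against as well, since leaving out each of the 6 arrays in turn after quantile normalization gave camera adjusted p values between 1.33e-07 and 0.00130. Of the 10 splits of the arrays, 1 (the real one) gave a camera p for this list as small (9.32e-09, the smallest other 0.00469), and 10 splits are too few for a share under 0.05. Lower ERK output under the drug stays a hypothesis that may account for the list, with an adjusted p of 0.408 with an estimated correlation and 0.103 after quantile normalization.

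The 9 lists that camera called lower only as deposited may reflect the narrower spread of the PD98059 arrays 2 and 3, in which bright genes read lower as a class. The median of their medians was -0.27 as deposited and -0.089 after quantile normalization. The lists were picked because they lost the call under that normalization, so this drop does not decide. As deposited, against random lists of equally bright genes, the medians of the 9 lists were not alike. Mitosis lay at percentile 68.07, oxidative phosphorylation at 49.56 and ribosome biogenesis at 34.49, near the middle of such lists. The p53 targets lay at 25.34, Hippo targets at 24.62, immediate early genes at 13.33, MAPK components at 12.27 and G1/S at 6.14. The unfolded protein response lay at 1.98 (1.69 after quantile normalization), lower than most such lists. A real fall in the genes of the 9 lists stays open too, because quantile normalization also removes any true shift shared by bright genes. Of the 10 splits, 1 (the real one) called as many as 18 lists, and the highest other called 15; 10 splits are too few for a share under 0.05.

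For single genes, 2 of the 10 splits gave as many as 1836 genes at an unadjusted p under 0.05. The highest, 4662, came from setting the DMSO arrays 1 and 3 with the PD98059 array 1 against the rest, and after quantile normalization this split still gave 2818 against 1644 for the real one, which points to a structure of the arrays outside the treatment. All 10 splits, the real one included, gave 0 genes past the adjusted threshold, with 0 as the highest of the others, and 10 splits are too few for a share under 0.05.

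CYP1A1 was the gene with the smallest unadjusted p. Its difference was 1.77 (SE 0.19) after quantile normalization, but this value is no test of the narrower spread. Genes of the class closest to its level (mean level 3.54) had a median difference of -0.16 as deposited. The narrower spread thus went against a rise, and removing it could not be expected to lower the difference. That direction argues against the narrower spread as the cause. Signal from its paralog CYP1A2 is argued against, since the paralog's own probe set differed by -0.10 (95% interval -0.50 to 0.30). Activation of the aryl hydrocarbon receptor, which flavones such as PD98059 might bring about, stays open. The other 12 measured targets had a mean difference of -0.19 as deposited and -0.056 after quantile normalization. Their 95% intervals over the 12 genes, -0.42 to 0.035 and -0.23 to 0.11, both hold 0. These 2 intervals measure the spread between genes, taken as independent, and not the spread between arrays. The list was fixed from targets known in other cells, and how many of them respond in AGS cells was not tested.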
